A study of Nematostella vectensis with 31 samples.

How the data were processed

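The series holds 31 samples of Nematostella vectensis: 30 bulk RNA libraries in 15 groups of 2 and 1 single-cell library. Per the labels, each bulk library was made from 200 whole planula larvae kept at 22 °C; mutants were made with Cas9 ribonucleoprotein at 500 ng/µL, and shRNAs were injected at 600 ng/µL into wild-type unfertilized oocytes. Wild-type larvae were spawned on the same date as the mutants and collected in parallel, per the labels. The column names of the wild-type 60 h libraries hold the word new, which nothing in the sources used here explains; they were used as wild type at 60 h.

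The bulk values are whole read counts per gene as deposited, made with bcl2fastq 2.18, STAR and featureCounts, per the submitters' processing notes, and not normalized, per the file headers. The single-cell values are UMI counts per gene and cell in the deposited filtered matrix, made with Cell Ranger 4.0 and STAR, per the submitters' processing notes. The genome build is not given in the sources used here; coordinates are the gene starts and ends in the count file, 1-based. The strand setting of the counting is not given either, so counts of genes that overlap others on the opposite strand are uncertain.

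Genes carry identifiers of the form NV2 and a number. The reference table pairs names with other identifiers, and 0 of its identifiers matched. The targeted genes Anthox1a, Anthox8, Anthox6a and Pbx could therefore not be located, so the labels were not checked by their counts, and the gene lists and cell type markers chosen by name were not analysed here.

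Of 24525 genes, 19997 passed the filter of filterByExpr (minimum count 10) in the mutant experiment and 18912 in the shRNA experiment, so 4528 and 5613 were left out. Library sizes were scaled by TMM. Each experiment was fitted with 1 mean per group (12 and 3 residual degrees of freedom) and tested with edgeR's quasi-likelihood F test with robust estimation, and p was adjusted by Benjamini-Hochberg within each comparison. Genes with an adjusted p under 0.05 are called, and changes of 2-fold or more were counted separately. The comparisons were each mutant against wild type on average over the times and at each time, the difference of that effect between times, wild type between times, each Pbx shRNA and their mean against the scrambled shRNA, and shRNA 2 against shRNA 1. These comparisons, their tests and the rule for naming genes were chosen before the data were examined. By that rule the text names, for each mutant mean, the Pbx mean and wild type at 72 h against 48 h, the 2 genes with the largest rise and the 2 with the largest fall among called genes with a mean log2 CPM (counts per 1e+06 counted reads) of at least 0 and every library on the same side of the mean of its control libraries. Fold changes of genes with no count in a group are lower bounds with 3 counts over that group as the floor, and for genes with few counts the text gives the ratio of pooled CPM with a 95% exact interval. In simulated counts with 200 changed genes, the test of a mutant's mean over times recovered 76.1% of changes of 1.25-fold and 100% of 2-fold. In the Pbx mean it recovered 44.8% and 97.0%. False calls made up 3.66% of all calls in the mutant mean and 10.1% in the Pbx mean. The share in the Pbx mean was above the rate set by the adjusted p threshold of 0.05.

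Lists of genes were tested with camera with a preset correlation of 0.01 and with an estimated correlation, and with fry. Overlaps were set beside the number that independent lists of the same size would share. Covariances and correlations were set beside 10 simulations of unchanged mutants that share the 6 wild-type libraries. Unevenness over chromosomes was tested against 10000 random sets with the same spread of mean expression, with changed genes no more than 5 genes apart also counted once. Transcript length is the summed exon length in the count file; the length trend of each library was removed as an offset from a lowess curve (span 0.3).

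In the single-cell library the filters of at least 300 genes per cell and 3 cells per gene kept all 10408 barcodes and 21093 genes; every barcode had at least 537 genes, so the cell filter tested nothing. A limit on mitochondrial counts could not be applied without gene names, and Scrublet marked 0 cells, so doublets were not removed. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 gave the clusters. A gene entered the list of the cluster where it was highest if it was at least 4-fold above all other cells and seen in at least 25% of the cluster's cells; clusters with at least 10 such genes were used. There is 1 single-cell library, so shares have exact binomial intervals and no test.

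Alternatives were DESeq2, DESeq2's size factors, no filter on low counts, replicate number as a block, fits of only the groups compared or of all 30 libraries, each library left out, other clustering settings and, added after the data were seen, a test against 1.5-fold, the length offset, means without the 60 h libraries and a time effect of 72 h against 48 h alone. Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9. On simulated data the gene tests of the Anthox1a mutant (mean and 72 h) and of the Pbx knockdown (mean and shRNA 1), camera with the preset correlation and the test of chromosomes were checked; the test of differences between times, fry and camera with an estimated correlation were not.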

Results

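RNA was measured in Nematostella vectensis, the starlet sea anemone, a cnidarian whose fertilized egg develops into a swimming planula larva. Each bulk library came from 200 whole planula larvae raised at 22 °C and held poly(A)-selected RNA. The first experiment compared homozygous mutants of 3 Hox genes, Anthox1a, Anthox8 and Anthox6a, with wild-type larvae at 48, 60 and 72 h after fertilization, with 2 libraries in each of 12 groups and 24 in all. Hox genes encode homeodomain transcription factors that set regional identity along a body axis. The second experiment measured 6 libraries of larvae at 72 h, 2 for each of 2 short hairpin RNAs (shRNAs) against Pbx and 2 for a scrambled shRNA, all injected into wild-type oocytes. Pbx encodes a homeodomain protein that binds DNA together with Hox proteins. A single-cell library held endoderm isolated from wild-type larvae at 72 h. The libraries of the mutant experiment held 32.0 to 54.4 M counted reads (M, 1e+06 reads; median 38.7 M), and those of the shRNA experiment 24.2 to 28.7 M.

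The 2 libraries of each group lay close together. Their counts had Spearman correlations of at least 0.995, and the chi-square of their counts divided by its degrees of freedom ran from 1.33 to 6.93, so every pair differed by more than sampling noise. The biological coefficient of variation was 3.41% in the mutant experiment and 4.50% in the shRNA experiment. Nothing in the labels says that the 2 libraries of a group came from separate spawnings or cultures. The p-values therefore measure only the spread between these libraries, which may be technical, and genotype cannot be separated from the stock or clutch of larvae. In the mutant experiment the first principal component carried 46.4% of the variance and followed time, from -57.5 and -60.1 in wild type at 48 h to 74.9 and 74.0 at 72 h. The second component carried 11.7% and set the Anthox1a mutant, at 30.5 to 49.4, apart from the other genotypes, all below 0. At 72 h the mutants lay lower than wild type on the first component, at 26.2 and 26.4 for Anthox1a, 27.6 and 25.1 for Anthox6a and 54.2 and 59.6 for Anthox8.

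**Figure D1:**
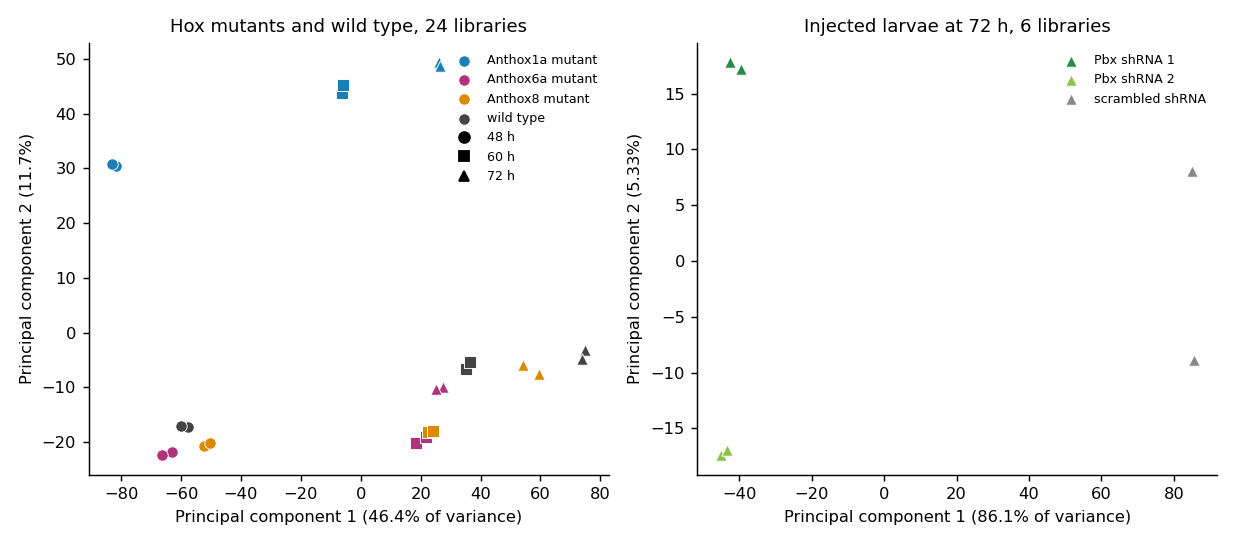
Principal components of log2 CPM (counts per 1e+06 counted reads) in the 24 libraries of mutants and wild type (left, colour for genotype and symbol for time) and the 6 shRNA libraries (right), with each component's share of the variance on its axis. The libraries spread by time along the first component on the left, and by Pbx against scrambled shRNA on the right, where that component carried 86.1% of the variance.

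On average over the 3 times the Anthox1a mutant differed from wild type in more genes than either of the other mutants. At 72 h alone the Anthox6a mutant had more calls, 10672 against 10027, and nearly the same number past 2-fold, 1663 against 1664. In the Anthox1a mutant most of the genes changed 2-fold or more on average were lower. Gene NV2.7824 (chromosome 13, bases 9680021 to 9682112, minus strand, 2 exons) had no count in any of the 6 mutant libraries and 9.93 ± 2.72 CPM (SD, n = 6) in wild type, so it was at least 840-fold lower. The floor was 3 counts over the mutant libraries. Gene NV2.5182 (chromosome 11, bases 11862981 to 11863802, plus strand, 1 exon) also had no count in the mutant against 5 ± 1.48 CPM (SD, n = 6) in wild type, at least 423-fold lower on the same floor. The rises named by the rule were at NV2.23378 (chromosome 8, bases 7015654 to 7016862) and NV2.23364 (chromosome 8, bases 6929088 to 6931128). Their log2 fold changes were 5.50 ± 0.22 and 2.79 ± 0.096 (SE). NV2.23378 stood at 5.34 ± 4.33 CPM (SD, n = 6) in the mutant and 0.116 ± 0.0949 (SD, n = 6) in wild type, and fell with time in the mutant from 10.8 CPM at 48 h to 1.57 at 72 h. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 9.6e-19 for NV2.23378, 6.2e-22 for NV2.23364, 3.6e-16 for NV2.7824 and 3.4e-23 for NV2.5182. In each case all 6 mutant libraries lay on the same side of the wild-type mean of their time, as the naming rule requires. Averaged over the 3 times, 11491 of 19997 tested genes had an adjusted p under 0.05, 5507 higher and 5984 lower in the mutant. Of these, 322 were at least 2-fold higher and 863 at least 2-fold lower, and 63 and 265 passed both criteria at all 3 times. Most called changes were small, with a median size of 0.249 on the log2 scale. Tested against a change of 1.5-fold, 1272 genes passed. In all, 3 genes had no count in the mutant and at least 1 CPM in every wild-type library, NV2.7824 and NV2.5182 among them.

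In the Anthox8 mutant the genes with the largest falls under the naming rule stayed almost silent at every time. Gene NV2.15250 (chromosome 3, bases 19746836 to 19752174, plus strand, 9 exons) had 5 counts in the 6 mutant libraries, 0.0171 ± 0.0191 CPM (SD, n = 6), against 7.36 ± 2.00 CPM in wild type (SD, n = 6). The ratio was 357 (95% exact interval 153 to 1100, counting error only). Gene NV2.12004 (chromosome 2, bases 11737430 to 11739223, plus strand, 2 exons) stood at 0.0324 ± 0.0384 CPM against 3.62 ± 2.79 (SD, n = 6 each), a ratio of 91 (interval 47.7 to 200). In wild type NV2.12004 rose from 0.331 CPM at 48 h to 6.53 at 72 h. Both Anthox8 libraries had no count at that time. The rises named by the rule were of NV2.25775 (sequence Un1, bases 525783 to 530133, minus strand, 1 exon), from 1.36 ± 0.222 to 8.01 ± 0.346 CPM (SD, n = 6 each), and NV2.5784 (chromosome 12, bases 3360480 to 3370696, minus strand, 8 exons), from 0.113 ± 0.051 to 2.51 ± 3.45 CPM (SD, n = 6 each). NV2.25775 changed by 2.57 ± 0.090 (log2, SE). The rise was not particular to Anthox8: at 72 h NV2.25775 stood at 4.39 CPM in the Anthox1a mutant and 0.0278 in the Anthox6a mutant, against 1.14 in wild type, and at 5.15 CPM in scrambled-shRNA larvae. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 5.6e-27 for NV2.15250, 8.7e-18 for NV2.12004, 2.3e-21 for NV2.25775 and 2.6e-08 for NV2.5784. Each had 6 of 6 mutant libraries on one side of the wild-type mean of their time, as the naming rule requires. Over the 3 times 8220 genes were called, 3863 higher and 4357 lower, 225 at least 2-fold higher and 324 at least 2-fold lower. The median size of a called change was 0.219 (log2), and 434 genes passed a test against 1.5-fold. At all 3 times 40 genes were 2-fold higher and 98 lower.

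In the Anthox6a mutant the genes with the largest falls under the naming rule were close to absent from every library. Gene NV2.7327 (chromosome 13, bases 4910753 to 4913355, plus strand, 1 exon) had 1 count in the 6 mutant libraries and 656 in the 6 wild-type libraries, a ratio of 635 (95% exact interval 114 to 25100, counting error only). It stood at 2.58 ± 0.439 CPM (SD, n = 6) in wild type, and at 72 h it also had no count in either Anthox1a library. Gene NV2.20066 (chromosome 6, bases 7460819 to 7476717, plus strand, 54 exons) stood at 0.0223 ± 0.0353 CPM against 3.00 ± 0.630 (SD, n = 6 each), a ratio of 149 (interval 63.5 to 460). The rises were of NV2.5784, from 0.113 ± 0.051 to 2.69 ± 3.79 CPM, and NV2.7602 (chromosome 13, bases 7506261 to 7507853, minus strand, 1 exon), from 2.60 ± 0.475 to 14.3 ± 7.31 CPM (SD, n = 6 each), a log2 fold change of 2.30 ± 0.21 (SE). The adjusted p (edgeR's quasi-likelihood test, Benjamini-Hochberg) was 8.7e-19 for NV2.7327, 4.3e-20 for NV2.20066, 1.3e-07 for NV2.5784 and 8.7e-07 for NV2.7602. Each had 6 of 6 mutant libraries on one side of the wild-type mean of their time, as the naming rule requires. Over the 3 times 9970 genes were called, 4585 higher and 5385 lower, 314 at least 2-fold higher and 502 at least 2-fold lower. The median size of a called change was 0.225 (log2), and 816 genes passed a test against 1.5-fold. At all 3 times 43 genes were 2-fold higher and 170 lower.

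**Figure D2:**
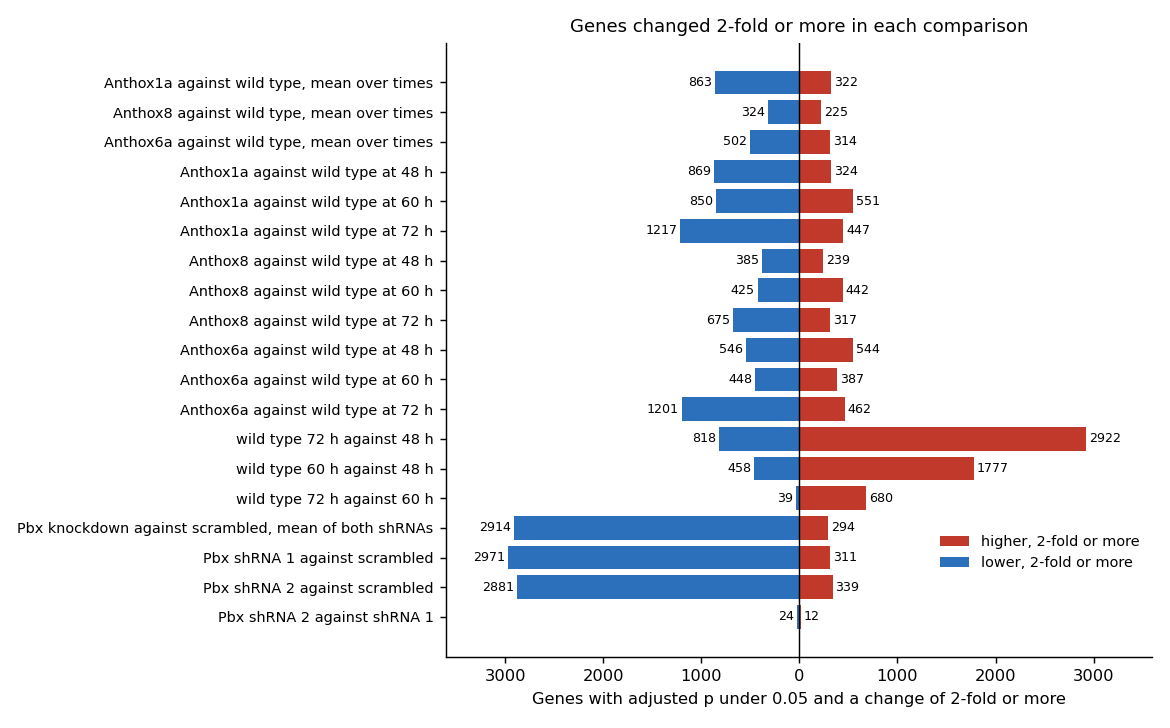
Number of genes with an adjusted p under 0.05 and a change of 2-fold or more in each comparison, with genes that were higher drawn to the right of 0 and genes that were lower to the left. Lower genes outnumber higher genes in each Pbx comparison against scrambled shRNA (2914 against 294 for the mean of both shRNAs), and the reverse holds for wild type over time.

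**Figure D3:**
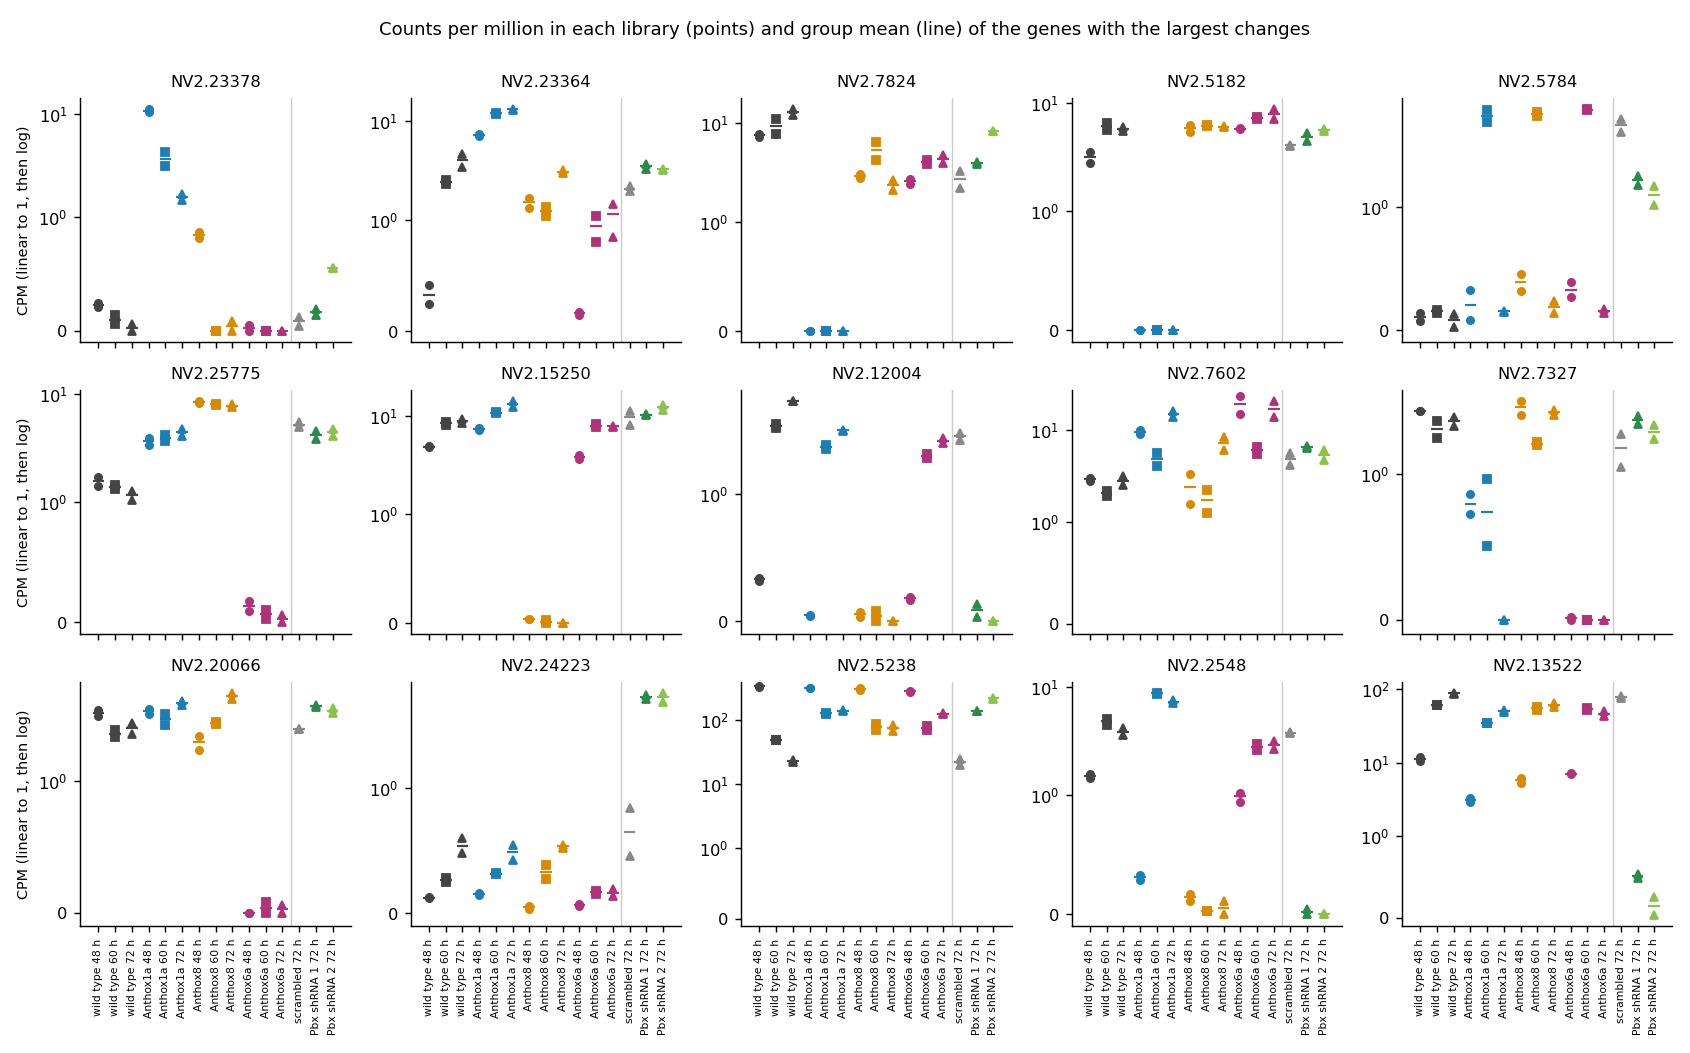
CPM of 15 of the genes named in the text, in each library (points; colour for genotype or shRNA, symbol for time) and as the mean of the 2 libraries of a group (line), on an axis that is linear up to 1 and logarithmic above. NV2.7824 and NV2.5182 are at 0 in all 6 Anthox1a libraries, and NV2.5784 is high at 60 h in each mutant but not in wild type.

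The effect of each mutation was tested for a difference between the 3 times. With edgeR's quasi-likelihood F test, 9757 genes differed in the Anthox1a mutant, 9862 in the Anthox8 mutant and 10326 in the Anthox6a mutant, and among these the log2 effects at different times lay at least 1 apart for 1914, 1651 and 2109 genes. Genes called in opposite directions at 48 h and 72 h numbered 1351, 1916 and 1300. In the Anthox1a mutant NV2.23364 was higher by 4.42 (log2) at 48 h, 2.27 at 60 h and 1.69 at 72 h, while NV2.23378 was higher by 5.57, 5.21 and 5.72. NV2.5784 stood at 6.67 ± 1.15 CPM in the Anthox1a mutant, 6.95 ± 0.477 in the Anthox8 mutant and 7.58 ± 0.107 in the Anthox6a mutant at 60 h, against 0.153 ± 0.0175 in wild type (SD, n = 2 each). At 48 h and 72 h all groups of the mutant experiment lay at or below 0.387 CPM for this gene, and scrambled-shRNA larvae at 72 h held 5.48 ± 1.04 CPM (SD, n = 2). More genes were 2-fold higher in all 3 mutants at 60 h, 148, than at 48 h, 44, or at 72 h, 43. The counterparts for lower genes were 54 at 60 h, 56 at 48 h and 174 at 72 h. The wild-type libraries at 60 h are the only ones whose column names carry the word new, which the sources used here do not explain.

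Wild-type larvae changed widely between 48 and 72 h, and most of the large changes were rises. Gene NV2.2681 (chromosome 10, bases 3365736 to 3377104) had no count at 48 h and 13.1 ± 0.198 CPM (SD, n = 2) at 72 h, at least 449-fold higher. Gene NV2.17193 (chromosome 4, bases 17002019 to 17003156) went from 1 count to 30 ± 0.176 CPM (SD, n = 2), a ratio of 3080 (95% exact interval 553 to 122000, counting error only). NV2.15097 (chromosome 3, bases 18404018 to 18406988) fell from 45.1 ± 1.97 to 1.38 ± 0.262 CPM, and NV2.5238 (chromosome 11, bases 12471089 to 12471965) from 338 ± 11.5 to 22.9 ± 1.56 CPM (SD, n = 2 each). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 3.7e-23 for NV2.2681, 1.4e-23 for NV2.17193, 7.7e-11 for NV2.15097 and 2.8e-12 for NV2.5238. Both later libraries lay on one side of the mean of the earlier ones, as the naming rule requires. At 72 h NV2.2681 stood at 3.52 CPM in the Anthox1a mutant, 6.84 in the Anthox8 mutant and 4.03 in the Anthox6a mutant, each below wild type. NV2.5238 stood at 141, 76.2 and 126 CPM, each above it. Both genes were picked by their change in wild type. The same wild-type libraries at 72 h serve that choice and the comparison with the mutants, so a deviation of those libraries would enter both. From 48 to 72 h 13922 genes were called, 2922 at least 2-fold higher and 818 at least 2-fold lower. From 48 to 60 h 11680 genes were called, with 1777 and 458 past 2-fold, and from 60 to 72 h 7186, with 680 and 39. The last count was 25 with DESeq2 and 42 to 86 with a library left out.

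The 3 mutants shared part of their changes. Pairs of mutants had 2-fold higher genes in common in 77 cases for Anthox1a and Anthox8, 99 for Anthox1a and Anthox6a and 76 for Anthox8 and Anthox6a, where independent lists would share 3.62, 5.06 and 3.53. For 2-fold lower genes the overlaps were 112, 220 and 67, where independent lists would share 14.0, 21.7 and 8.13. Genes 2-fold changed in opposite directions numbered 43, 45 and 36, also more than independent lists of these sizes would share. The excess was therefore not limited to changes in the same direction. In all 3 mutants 42 genes were 2-fold higher and 40 lower, where independent lists would share 0.0569 and 0.351. The mutants were compared with the same 6 wild-type libraries, so part of the excess may come from the shared controls. Across 19997 genes, which are not independent replicates, the log2 changes of a pair had covariances of 0.0779, 0.131 and 0.0612 and correlations of 0.303, 0.430 and 0.286, where simulated unchanged mutants gave covariances of 0.0116, 0.0116 and 0.0115 and correlations of 0.498, 0.490 and 0.485. With a separate wild-type library per time for each mutant of a pair, the 2-fold overlaps were 61, 81 and 61 for higher genes. For lower genes they were 93, 180 and 58. The simulations held only the spread between the libraries of a group. A deviation common to both wild-type libraries of a time is absent from the simulations and stays in with separate libraries. The size of the part from shared controls therefore stays open.

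Genes changed 2-fold at all 3 times were spread unevenly over the chromosomes. In the Anthox8 mutant 35 of 138 such genes (25.4%) lay on chromosome 3, which holds 8.74% of the tested genes, and in the Anthox6a mutant 44 of 213 (20.7%) lay on chromosome 6, which holds 7.12%. In the Anthox1a mutant chromosome 3 held 49 of 328 (14.9%). This was a weaker excess, 1.71-fold against 2.9-fold in each of the other 2 cases, and 1.45-fold with neighbours counted once. Among the numbered chromosomes the highest share in this mutant was on chromosome 15, with 29 of 888 tested genes changed (3.27%), against 2.8% on chromosome 3. A stretch of chromosome 15 (bases 9000001 to 10000000) held 13 changed genes among 92 tested. The stretch with the most changed genes in the Anthox6a mutant was at the start of chromosome 7 (bases 1 to 1000000), with 9 of 45. The highest shares were on the sequences outside the 15 numbered chromosomes, where 6 of 45 tested genes (13.3%) had changed in the Anthox1a mutant, 5 (11.1%) in the Anthox8 mutant and 3 (6.67%) in the Anthox6a mutant. In 10000 random sets of genes matched on mean expression, the permutation p of the unevenness was 1e-04 for each mutant, the smallest that these sets can give. It was the same on the numbered chromosomes alone. With them, chi-square over its degrees of freedom was 6.88, 10.7 and 6.85 for Anthox1a, Anthox8 and Anthox6a; without them it was 4.77, 6.59 and 6.47. The named genes NV2.15250 on chromosome 3 in the Anthox8 mutant and NV2.20066 on chromosome 6 in the Anthox6a mutant were among the genes lower at all 3 times on these chromosomes.

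**Figure D4:**
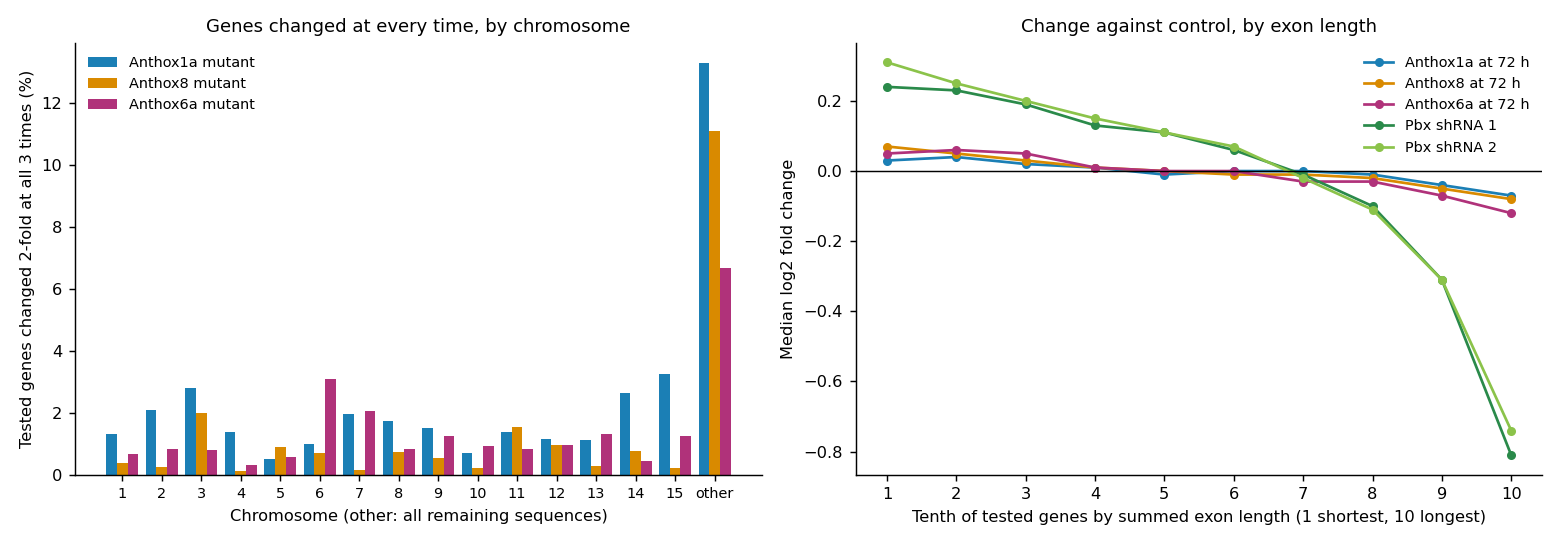
Left, percentage of the tested genes on each chromosome that changed 2-fold at all 3 times in each mutant (bars; other stands for the 45 tested genes on remaining sequences). Right, median log2 fold change at 72 h of the tested genes in 10 bins by summed exon length (lines), where the longest bin lies at -0.81 and -0.74 for the Pbx shRNAs and between -0.12 and -0.07 for the mutants.

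Knockdown of Pbx was followed at 72 h by far more large falls than rises. Gene NV2.13522 (chromosome 3, bases 4209744 to 4217215, minus strand, 7 exons) stood at 78.0 ± 3.33 CPM (SD, n = 2) in scrambled-shRNA larvae, 0.511 ± 0.0375 with shRNA 1 and 0.148 ± 0.157 with shRNA 2 (SD, n = 2 each). Gene NV2.2548 (chromosome 10, bases 2033417 to 2036407, minus strand, 1 exon) had 181 counts with the scrambled shRNA and 1 in the 4 knockdown libraries, a ratio of 411 (95% exact interval 72.9 to 16300, counting error only). NV2.24223 (chromosome 8, bases 15021711 to 15026306, minus strand, 6 exons) rose from 0.646 ± 0.267 (SD, n = 2) to 6.30 ± 0.546 CPM (SD, n = 4), a log2 fold change of 3.28 ± 0.22 (SE). NV2.5238 rose from 22.2 ± 2.91 (SD, n = 2) to 180 ± 45.3 CPM (SD, n = 4), a log2 fold change of 2.98 ± 0.062 (SE). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 6.5e-16 for NV2.13522, 7.7e-10 for NV2.2548, 4.4e-09 for NV2.24223 and 6.1e-15 for NV2.5238. Each had 4 of 4 knockdown libraries on one side of the control mean, as the naming rule requires. Of 18912 tested genes 12954 were called for the mean of both shRNAs. Of these, 294 were at least 2-fold higher and 2914 at least 2-fold lower, so 90.8% of the genes past 2-fold were lower. In all, 3905 genes passed a test against 1.5-fold. The shRNAs gave similar counts, 12268 calls for shRNA 1 and 12187 for shRNA 2, with 2971 and 2881 genes at least 2-fold lower. Both were compared with the same 2 scrambled-shRNA libraries, so a deviation of those libraries would enter both counts. That pair was the least alike of all groups, with a chi-square over its degrees of freedom of 6.93. Between the shRNAs 850 genes were called, 12 at least 2-fold higher with shRNA 2 and 24 lower; with 1 of the 4 libraries left out, 126 to 160 were called.

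The falls after Pbx knockdown were concentrated among genes with long transcripts. In the 10% of genes with the longest summed exons (5307 to 47294 bases) the median log2 fold change was -0.78 and 42.3% were at least 2-fold lower, while in the shortest 10% (203 to 1130 bases) the median was 0.28 and 11.9% were at least 2-fold lower. At 72 h the longest 10% lay at -0.07, -0.08 and -0.12 in the Anthox1a, Anthox8 and Anthox6a mutants. Set beside wild-type larvae at 72 h from the other experiment, the longest 10% lay at 0.13 in scrambled-shRNA larvae, -0.59 with shRNA 1 and -0.55 with shRNA 2. With a trend on length removed from every library, 328 genes were 2-fold higher and 2647 lower.

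Several genes changed in the same direction in a Hox mutant and after Pbx knockdown. NV2.2548 stood at 0.0546 ± 0.0772 CPM in the Anthox8 mutant at 72 h against 3.86 ± 0.404 in wild type (SD, n = 2 each). In the Anthox1a mutant it was higher than in wild type, at 7.34 ± 0.333 CPM (SD, n = 2). NV2.12004 stood at 0.0883 ± 0.0707 CPM with Pbx shRNA 1 and at 0 with shRNA 2, against 3.23 ± 0.330 with the scrambled shRNA (SD, n = 2 each). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment NV2.2548 had an adjusted p of 6.4e-16 in the Anthox8 mutant at 72 h and NV2.12004 of 3.5e-09 in the Pbx knockdown. Of the genes 2-fold lower at 72 h, a part was also 2-fold lower in the Pbx knockdown, against 15.4% of all genes tested in both. This part was 448 of 1062 in the Anthox1a mutant (42.2%), 188 of 612 in the Anthox8 mutant (30.7%) and 484 of 1075 in the Anthox6a mutant (45.0%). For genes 2-fold lower on average it was 42%, 23.3% and 35.9%. For genes 2-fold lower at all 3 times it was 86 of 247 (34.8%), 20 of 92 (21.7%) and 31 of 158 (19.6%). The last 2 shares lay near that of all genes. Genes 2-fold higher at 72 h were also 2-fold higher in the Pbx knockdown in 46 of 372 cases, 22 of 268 and 52 of 385, where independent lists would share 5.68, 4.09 and 5.88. Some overlaps ran the other way: of 155 genes 2-fold higher on average in the Anthox8 mutant, 47 (30.3%) were 2-fold lower in the Pbx knockdown and 4 were 2-fold higher, where independent lists would share 23.8 and 2.37. Across 18860 genes, which are not independent replicates, the mutant changes at 72 h and the Pbx changes correlated. The values were r = 0.276 for Anthox1a, 0.248 for Anthox8 and 0.344 for Anthox6a (Spearman's rho 0.416, 0.409 and 0.470). The 72 h mutant changes also ran against the time change of the other 2 mutants (r = -0.347, -0.171 and -0.406). The Pbx changes ran against that of wild type from 48 to 72 h (r = -0.311). A shared part from development stays open. The genes called higher and those called lower in each mutant, on average and at 72 h, made 12 lists. For the mean of both shRNAs each of the 12 moved in its own direction by camera with a preset correlation of 0.01. With an estimated correlation the 6 lists of lower genes kept their call (adjusted p 0.017 to 0.035) and the 6 lists of higher genes lost it (adjusted p 0.063 to 0.29). The genes called higher on average in the Anthox8 mutant had a median of 0.12 and a mean of -0.15 (log2) in the knockdown, and fry gave them the opposite direction with an adjusted p of 0.11. With shRNA 1 alone this list lost its camera call (adjusted p 0.099), and fry called it lower (adjusted p 0.042). Of the 12 lists limited to 2-fold changes, 8 moved in their own direction with the preset correlation and 0 with an estimated correlation (adjusted p of at least 0.22). With each shRNA alone 7 did so with the preset correlation, since the genes 2-fold lower on average in the Anthox8 mutant lost their call (adjusted p 0.051 and 0.053). The genes 2-fold higher on average in the Anthox8 mutant fell in the knockdown, with 62 called lower and 10 higher of 155 (camera adjusted p 0.026), a call that was lost with an estimated correlation (adjusted p = 0.22). The 2 experiments shared no library.

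The endoderm library held 10408 barcodes with a median of 2755.5 unique molecular identifiers (UMIs) and 1116.5 genes per cell. The 91.2 M UMIs were unevenly distributed, and 87 cells with more than 100000 UMIs carried 19.4% of them. Clustering gave 22 clusters of 12 to 1692 cells. In cluster 11 (320 cells, 3.07% of cells, 95% exact interval 2.75 to 3.42% for counting error only) the leading gene NV2.20021 was seen in 85.0% of its cells and 5.40% of the other cells, and in cluster 9 (343 cells, 3.30%, interval 2.96 to 3.66%) the leading gene NV2.16299 was seen in 95.3% and 5.41%. The genes of a cluster that were at least 4-fold above all other cells and seen in at least 25% of its cells made a list for 17 clusters, 1595 genes in all; 48.6% of the cells were in the 5 clusters without a list. Cell types were not named, since the sources used here pair no gene identifier with a gene name. Among the genes named above, NV2.2681, which rose in wild-type development, had 11633 of its 13318 UMIs in cluster 5, 986 CPM there (95% exact interval 968 to 1000, counting error only) against 21.2 CPM in all other cells. It was seen in 9.59% of the cells of cluster 5 and 3.69% of the other cells, so a small share of cells carried these UMIs. The share of UMIs from RNA outside the cells was not estimated, and the best match of cluster 5 under another setting shared as little as 0.394 of its cells (Jaccard index).

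Several of these lists were lower in the mutants at 72 h and higher in wild type at 72 h than at 48 h. Both comparisons use the same 2 wild-type libraries at 72 h with opposite signs. A deviation of those libraries alone could give such a pattern, and its size was not tested. The list of cluster 14 had 53 of 64 tested genes called lower and 2 called higher in the Anthox1a mutant at 72 h, with a median log2 change of -0.51, and 53 lower and 3 higher in the Anthox6a mutant, with a median of -0.46. The list of cluster 9 had 102 of 141 genes lower and 5 higher in the Anthox1a mutant (median -0.39), 112 lower and 4 higher in the Anthox6a mutant (median -0.42), and 92 lower and 12 higher in the Anthox8 mutant (median -0.30). The list of cluster 16 had 40 of 49 genes lower and 0 higher in the Anthox6a mutant (median -0.78). By camera with an estimated correlation the adjusted p for cluster 14 was 0.0057, 0.044 and 0.0098 in the Anthox1a, Anthox8 and Anthox6a mutants, for cluster 9 it was 9e-04, 0.0097 and 0.00074, for cluster 16 in the Anthox6a mutant 0.0029, and for cluster 22 0.00027, 0.011 and 0.00074. On average over the 3 times the calls were lost in the Anthox8 mutant (adjusted p = 0.072 for cluster 9, 0.38 for cluster 14 and 0.26 for cluster 22 with an estimated correlation). In the Anthox6a mutant that of cluster 14 was lost on average (median -0.11, adjusted p = 0.28 with an estimated correlation). In wild type the list of cluster 16 rose by a median of 2.28 (log2) from 48 to 72 h, that of cluster 14 by 1.17 and that of cluster 9 by 0.79, with adjusted p of 0.001, 0.0025 and 0.001 by camera with an estimated correlation. The list of cluster 7 had 17 of 19 genes higher and 0 lower in the Anthox6a mutant at 72 h with a median of 0.74, a call that was lost with an estimated correlation (adjusted p = 0.27). In the Pbx knockdown the list of cluster 16 had 34 of 49 genes lower and 6 higher (median -0.85) and an adjusted p of 0.00037 with the preset correlation, which was lost with an estimated correlation (adjusted p = 0.45), as were the calls of clusters 7, 10, 14, 18 and 22. Cluster membership depended on the settings: the best match of cluster 14 under another setting at the same resolution shared as little as 0.270 of its cells (Jaccard index), of cluster 16 0.244, of cluster 7 0.0726 and of cluster 22 0.0130, while for cluster 9 it was 0.552.

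**Figure D5:**
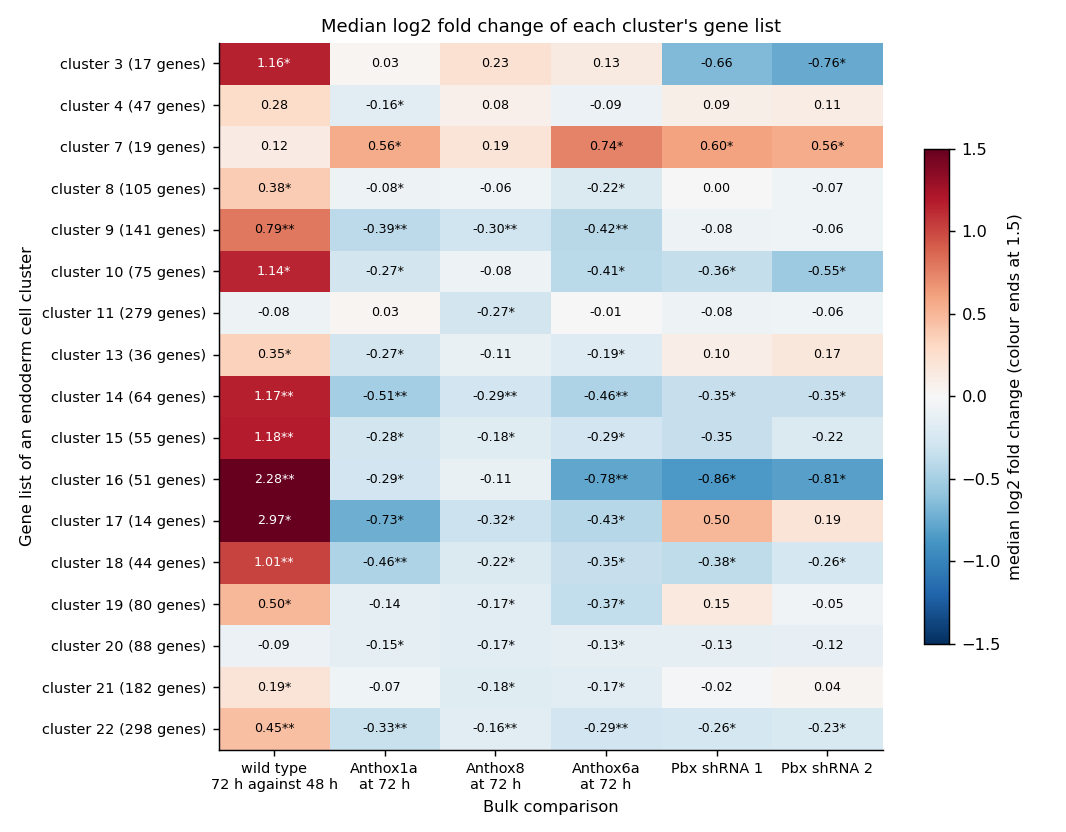
Median log2 fold change of the genes listed for each endoderm cluster (rows, with the number of genes) in 6 bulk comparisons (columns), where 1 star marks an adjusted p under 0.05 by camera with the preset correlation and 2 stars also with an estimated correlation. The lists of clusters 9, 14 and 22 carry 2 stars in wild-type development, where they rose, and in each mutant at 72 h, where they fell. These comparisons share the wild-type libraries at 72 h with opposite signs, so their opposed directions are not independent.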

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

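Tests of neighbouring copies, inherited stretches, the numbered chromosomes alone, slower development and the length correction were chosen after the results were seen; those of library scaling, of length among evenly expressed genes and of other splits were chosen before.

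A difference between groups marked these results for a closer look. The effect of the mutation differed between times for 9757 genes in the Anthox1a mutant, 9862 in the Anthox8 mutant and 10326 in the Anthox6a mutant. The 2 Pbx shRNAs differed in 850 genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the effect differed between times for NV2.23364 in the Anthox1a mutant (adjusted p 4.9e-09), NV2.5784 in the Anthox8 mutant (6.5e-05) and the Anthox6a mutant (2.2e-05) and NV2.12004 in the Anthox8 mutant (3.6e-05).

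The genes changed 2-fold at all 3 times were uneven over the chromosomes in each mutant. Runs of neighbouring gene copies as the cause were argued against: with neighbours counted once the permutation p stayed at 2e-04 for Anthox1a, 1e-04 for Anthox8 and 4e-04 for Anthox6a. Inherited chromosome stretches that differ between mutant and wild-type stocks stay open and fitted the test: chi-square over its degrees of freedom was 4.26, 9.93 and 4.96 for genes changed at all times, and 1.25, 0.641 and 1.19 for genes changed at 72 h alone (3.18, 4.01 and 4.05 against 1.14, 0.613 and 1.27 on the numbered chromosomes alone). Effects of the Hox mutation on genes near each other also stay open as untested, since each mutant is 1 stock.

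At 72 h many changes in each mutant ran against the change of the other 2 mutants from 48 to 72 h. That time change comes from larvae that are themselves mutant. In the Anthox8 mutant 27.4% of the 2-fold changes were of genes with little such time change, and 23.7% ran along it. Slower development or earlier staging as the whole cause was argued against in the Anthox8 mutant, where 48.9% of the genes changed 2-fold moved against the time change of the other 2 mutants. In the Anthox1a and Anthox6a mutants, with 65.8% and 69.7%, it cannot be told apart from an effect of the mutation, since the shares lie between the limits set for the test. A part of the changes may come from development in all 3 mutants, and a loss of Hox function that holds back endoderm genes was not tested.

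After Pbx knockdown 90.8% of the 2-fold changes were falls, and the longest transcripts fell most. Library scaling as the whole cause was argued against. After the shift of 0.45 (log2) that made the 2-fold counts equal, the ratio of 4-fold falls to rises was 8.08 (638 against 79). The shift removes the excess of 2-fold falls by construction (1788 against 1792), so a part from scaling stays open. Slower development as the whole cause was argued against likewise, since 52.3% of the fallen genes rose in wild type. A length bias as the whole cause was argued against too, with 89.0% still lower after the length correction. For the trend with length itself such a bias stays open and fitted its test, made on 1806 genes expressed evenly over the endoderm clusters. Of these, 132 were in the longest 10% of all tested genes and 1048 in the shorter 50%. The long ones had a median log2 change of -0.07, with 53% below 0, and the short ones of 0.44. The difference of -0.51 (95% bootstrap interval -0.64 to -0.36) was smaller than the -0.96 over all genes. These medians are relative to the TMM scaling, so they do not tell whether long genes fell or short genes rose. A part from slower development also stays open (35.8% of all genes rose in wild type, and the changes correlated with r = -0.311), as does an untested effect of Pbx on long genes.

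Other splits of the 12 libraries within times gave no count of calls as large as the real split, which was the only 1 of 100 to reach it in each mutant. The real splits called 11757, 7709 and 9482 genes for Anthox1a, Anthox8 and Anthox6a. The highest other splits, which exchanged the genotypes at whole times, called 9394, 7583 and 7635. Only 2 of the other splits in each mutant did so. The rest mixed the close libraries of a group, which widens the residual spread. The median over all other splits was 0, 0 and 2 calls. The rank therefore cannot speak to differences between clutches of larvae.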

How the results depend on the processing

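The tests against 1.5-fold, the length correction, the means without 60 h and the time effect of 72 h against 48 h alone were chosen after the results were seen. All 336 values of named genes under the alternatives kept their direction and their side of the threshold, where a missing adjusted p counted as kept. The naming rule picks the largest called changes with every library on one side, so such stability was close to assured. Of the counts of calls, 0 of 60 moved by over 1.5 times with DESeq2's size factors, with no filter on low counts, with the replicate block or with the length correction, 0 of 48 with only the groups compared, 4 of 60 with DESeq2, 0 of 9 without 60 h, 0 of 3 for 72 h against 48 h alone, 2 of 12 with all 30 libraries in 1 fit and 13 of 342 with a library left out. Tested against 1.5-fold, 1272 genes passed for Anthox1a, 434 for Anthox8, 816 for Anthox6a, 4787 for wild type at 72 h against 48 h and 3905 for the Pbx mean, fewer by the construction of the test. Between the shRNAs, 1703 genes were called (31 at least 2-fold higher) with all 30 libraries in 1 fit; DESeq2 gave 3 higher and 14 lower, and leaving out each of the 4 libraries gave 126 to 160 calls, 1 to 3 higher and 7 to 10 lower, with fewer samples and the lone sample assumed to vary like the other groups. DESeq2 gave 151 genes 2-fold higher in the Anthox8 mutant at 48 h and 25 lower in wild type at 72 h against 60 h, which ranged from 42 to 86 with a library left out; the cause was not tested. With an estimated correlation 6 of the 12 Hox lists kept their call in the Pbx knockdown. Leiden resolutions of 0.5 and 2 gave 14 and 38 clusters, and the other settings 20 to 25. Replicate numbers did not pair libraries: correlations of replicate differences between groups ran from -0.274 to 0.194 in 66 pairs of the mutant experiment, 6 over 0.1, and from -0.0032 to 0.0703 in 3 pairs of the shRNA experiment. The block changed 0 calls of the cluster lists. In simulated counts 44.8% of 1.25-fold changes were recovered in the Pbx mean and 76.1% in a mutant mean; the simulations differ in the number of libraries and the spread as well as in depth, and the effect of depth alone was not tested.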

Other observations

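All values here were chosen after the results were seen, apart from the named genes.

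Some named genes changed in a further comparison. NV2.2681 fell from 9.51 ± 1.61 CPM with the scrambled shRNA to 0.645 ± 0.261 with Pbx shRNA 1 and 0.907 ± 0.183 with shRNA 2 (SD, n = 2 each). NV2.17193 stood at 30 ± 0.176 CPM in wild type at 72 h (SD, n = 2). It stood at 8.25 ± 0.946 in the Anthox1a mutant, 9.91 ± 0.0501 in the Anthox8 mutant and 6.13 ± 0.0163 in the Anthox6a mutant (SD, n = 2 each). The low level was not particular to the mutants: scrambled-shRNA larvae at 72 h held 8.13 ± 1.55 CPM (SD, n = 2). The gene was also picked by its rise in the same wild-type libraries. NV2.23378, raised in the Anthox1a mutant, also stood at 0.839 ± 0.0344 CPM in the Anthox8 mutant at 48 h against 0.224 ± 0.0247 in wild type (SD, n = 2 each), but had no count in that mutant at 60 h and stood at 0.0436 ± 0.0617 against 0.0284 ± 0.0401 CPM at 72 h. NV2.7824, absent in the Anthox1a mutant, stood at 12.9 ± 1.15 CPM in wild type at 72 h (SD, n = 2). It was lower in the Anthox8 mutant (2.36 ± 0.371 CPM) and the Anthox6a mutant (4.33 ± 0.581 CPM; SD, n = 2 each). Scrambled-shRNA larvae at 72 h, from wild-type oocytes, were as low, at 2.73 ± 0.742 CPM (SD, n = 2).

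The list of cluster 11 had 198 of 279 genes lower and 7 higher in the Anthox8 mutant at 72 h (median -0.27), a call that was lost with an estimated correlation (adjusted p = 0.098). In the Anthox1a and Anthox6a mutants its medians were 0.03 and -0.01.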
